A study of Dugesia japonica with 4 samples.

How the data were processed

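Visium libraries of fresh-frozen Dugesia japonica head blastema were analysed, 4 in all and of 1 group. Per the file headers, the deposited matrices are raw UMI counts per feature and spot written by Space Ranger 2.0.1. The submitters' processing notes also name Seurat, with no step given for it. The genome build and annotation are not given in the sources used here. The deposited counts cover only spots that Space Ranger's tissue detection marked as lying on tissue, which was checked against the deposited spot positions. Of the 38792 features, 28999 carry a DJKW identifier and 9793 a Maker identifier, and the latter took 0.988% ± 0.0525 (SD, n = 4) of the UMIs. The name column repeats the identifier for every feature. None of the 232 gene names in the 15 lists of cell type, pathway and RNA quality markers fixed before the data were examined occurs among the features, and neither does Tcf4, the gene in the title of the series. The planned tests of those lists, of their co-occurrence and of Tcf4 were therefore not run, and signs of RNA quality such as mitochondrial or stress genes could not be followed.

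Depth was 11838407 UMIs over 1216 spots, from 1499569 UMIs in well A to 4395756 in well C, so the values of wells A and B rest on fewer UMIs. Intervals and limits cover counting error only. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom over genes being 11.5, between wells C and D.

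Zones were set from positions alone. A spot with tissue on all 6 neighbouring positions was interior (334 spots) and one with at least 1 neighbouring array position off tissue was edge (882 spots). Counts were summed per library and zone, giving 8 columns, and fitted with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F-test) with library and zone as terms, because both zones come from the same sections. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors were taken as the fold change over the square root of F. CPM are counts scaled to a common library total with TMM factors. The pairing is by design, since edge and interior spots lie on the same sections of the same well. The rule for naming genes was adjusted p under 0.05, one direction in every library tested (4 of 4, and 3 of 3 for region 5) and a mean of at least 50 CPM, ordered by fold. It allowed 2 identifiers per direction, or 2 for a region or for Moran's I, where no names are given. The other identifiers in the text are the most abundant feature and those of the added comparisons.

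Moran's I was computed per gene and library on the graph of 6 neighbours from log1p counts scaled to the median spot, with its expectation subtracted, for genes with a UMI in at least 10% of spots in every library. The 4 values per gene were tested against 0 with limma 3.58.1 with a trend on expression. RNA that spreads between neighbouring spots also raises I and was not separated.

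For the regions, each UMI was put at random, at 50%, into a clustering or a testing set. Spots were clustered on the clustering set with scanpy 1.11.5 (2000 variable genes, centring per library, 15 principal components, 15 nearest neighbours, Leiden resolution 0.6). Sums per region and library of the testing set were tested with edgeR as above. A library entered with at least 5 spots in and outside the region. A minimum of 20000 UMIs per sum was added after a test on simulated data, because smaller sums gave false calls without any structure. The sizes of the real sums were known by then, and the minimum leaves region 8 untested. No doublet caller was run, since spots are not cells.

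The scripts were tested on simulated data. For edge against interior, 90% of genes changed 2-fold and 43% of those changed 1.5-fold were recovered among 8712 genes, with 7 false calls. The changes were planted only in genes with a mean of at least 20 counts per column, so recovery of scarcer genes was not measured. All genes were simulated with a common dispersion, while real genes can vary more. The test of Moran's I had low power. In a first simulation it recovered 4.04% of genes 2-fold higher inside and 1.03% of those 1.5-fold higher among 5669 genes, with 1 false call. A second simulation, made easier after that result with larger folds in genes of at least 2000 UMIs, recovered 54.3% of genes 8-fold higher and 12.8% of those 4-fold higher among 5693 genes, with 2 false calls. For a planted region of genes 4-fold higher, all of at least 2000 UMIs, 100% of 200 genes were recovered among 6904 tested, with 11 false calls. Spots for Moran's I and the regions were simulated with counting (Poisson) noise alone around the profile of each library. These rates need not hold for real spots, which can vary more. Spots simulated without structure gave 2 calls over 2 regions in the testing set and 0 when the clustering set was tested on itself, so this simulation does not show that the split lowers false calls.

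Alternatives covered DESeq2 1.42.0, library totals, the filter on low counts, the block, the zone rules, thinning, the most abundant genes, shallow spots, the neighbour graph, the clustering settings and leaving out each library. Alternatives without isolated spots, without wells A and B or with edge spots matched one to one to interior spots by UMIs, the version of Moran's I with permutations within pieces subtracted, and the comparisons between sides and between the middle and the ends of sections were added after seeing the data.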

Results

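The data are spatial transcriptomes of the regenerating head of wild-type Dugesia japonica, a freshwater planarian flatworm that can rebuild a lost head. The sampled tissue is the head blastema, the mass of new tissue that grows at an amputation wound, at a time labelled 5 dpa. Frozen sections 8 µm thick were laid on Visium arrays, which capture polyadenylated RNA on a hexagonal grid of barcoded spots, so that each count belongs to a gene and a position. A spot is a small area of tissue that can hold several cells of different types. The series holds 4 libraries, here called wells A, B, C and D, and all 4 belong to 1 group, so no contrast between treatments or genotypes exists in them. The stated purpose was to chart gene expression across the tissue, and the comparisons below are therefore between places within the sections. The deposited feature lists give each gene model only as an identifier, with no symbol, so genes are named by identifier and nothing is said of their function.

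Well A held 180 tissue spots and 1499569 unique molecular identifiers (UMIs), the counts of single captured RNA molecules. Well B held 201 spots and 2190105 UMIs, well C 402 spots and 4395756 UMIs, and well D 433 spots and 3752977 UMIs. The median spot carried between 7672 UMIs in well D and 10281 UMIs in well B, and the median number of genes per spot was 2800 ± 327 (SD, n = 4). Of the 38792 features, 18670 had a UMI in at least 1 library and 12268 in every library. In each well, 12 groups of at least 5 connected spots were found, called sections here, which makes 48. In well B, 4 of these groups held 5 to 10 spots and were not told apart from fragments of a section, so the number of sections there is not certain. Sections had a median of 14.0 spots in well A, 17.5 in well B, 34.5 in well C and 35.0 in well D. Another 53 spots lay in groups of under 5 connected spots, with median UMI counts from 135 in well A to 731 in well C. The most abundant feature in all 4 wells was DJKW.19663, named after its values were seen, which took 5.10% ± 1.78 (SD, n = 4) of all UMIs. Whole-library profiles of wells B, C and D correlated with each other more closely (Pearson r over 12134 genes, 0.954 to 0.98) than those of well A did with any of them (0.835 to 0.887). These correlations are across genes, which are not independent replicates. The labels do not say whether the 4 libraries come from different animals, so the p-values of the comparisons across libraries concern only these libraries. Those of edgeR and limma also draw on a spread estimated over all genes together, and not on a single gene's spread between libraries alone.

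The first comparison asked which genes differed between the rim and the inside of the sections. An edge spot touched at least 1 position off the tissue and an interior spot had tissue on all 6 sides. Interior spots expressed 1351 genes at a higher level than edge spots and edge spots expressed 1142 genes at a higher level than interior spots, out of 8636 tested. These calls used edgeR's quasi-likelihood test on summed counts with the library as a block and a Benjamini-Hochberg adjusted p under 0.05. At 2-fold or more, 695 genes were higher inside and 778 were higher at the edge. The genes higher inside supplied 41.7% ± 13.2 (SD, n = 4) of the UMIs of interior spots and 22.3% ± 6.06 of those of edge spots. The genes higher at the edge supplied 13.8% ± 0.759 of the UMIs of edge spots and 5.73% ± 1.66 of those of interior spots. These shares are of genes chosen by the same counts, so they describe the calls and do not test them.

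DJKW.7912 showed the largest rise towards the inside among genes that passed the naming rule, at 1085 ± 1289 CPM (counts scaled to a common library total) in interior and 141 ± 135 in edge spots (SD, n = 4). Its log2 fold change was 2.78 ± 0.16 (SE, edgeR adjusted p = 8.65e-08), a 6.85-fold difference. DJKW.24046 followed, with 1125 ± 1396 CPM inside and 157 ± 169 at the edge and a log2 fold change of 2.76 ± 0.19 (edgeR adjusted p = 2.45e-07). The order of these genes turned with DESeq2 (log2 fold changes 2.78 for DJKW.7912 and 2.84 for DJKW.24046). It also turned without well B, well C or well D. The SDs of both genes were large because their levels differed between wells, from 101 CPM in the interior of well A to 2919 CPM in that of well D for DJKW.7912. Within each well the interior exceeded the edge, with log2 ratios of 2.27 to 3.27 for DJKW.7912 and 2.29 to 3.70 for DJKW.24046. In the other direction, DJKW.26548 stood at 589 ± 180 CPM at the edge and 44.9 ± 36.2 inside, 12.5-fold higher at the edge (log2 fold change -3.64 ± 0.20, edgeR adjusted p = 6.56e-08). DJKW.11951 stood at 110 ± 35.9 CPM at the edge and 10.2 ± 4.23 inside (log2 fold change -3.28 ± 0.19, edgeR adjusted p = 7.99e-08). All 4 genes moved the same way in 4 of 4 libraries, as did 2077 of the 2493 called genes.

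**Figure D1:**
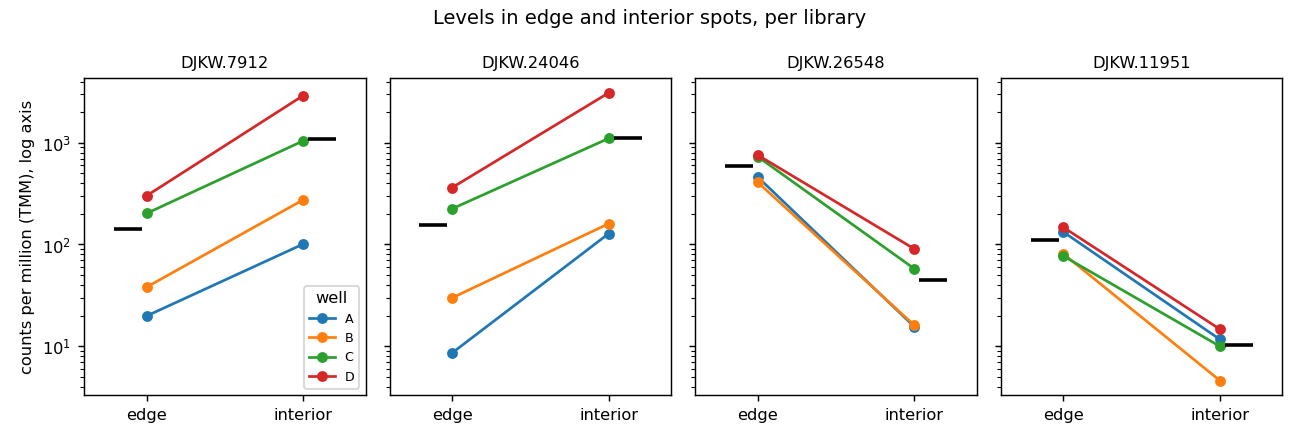
Level of 4 genes in edge and interior spots, in CPM after TMM scaling on a log axis. Each coloured line joins the edge and interior sums of 1 well, and black dashes mark the mean of the 4 wells. DJKW.7912 and DJKW.24046 rise and DJKW.26548 and DJKW.11951 fall towards the inside in 4 of 4 wells.

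The balance between the directions depended on the settings. The log2 differences of the 4 genes were smaller in an alternative that changed the weight of spots, the scale and the tool together. On the mean over spots of log-normalised values, where 1 is added to each scaled count before the logarithm, the log2 differences were 1.06 for DJKW.7912, 0.98 for DJKW.24046, -0.61 for DJKW.26548 and -0.62 for DJKW.11951 (limma adjusted p = 2.77e-03, 2.54e-03, 9.99e-04 and 7.28e-05). With TMM, 54.2% of the called genes were higher inside. With library totals alone the calls were 802 inside and 2865 at the edge (21.9% inside), and with limma on the mean over spots of log-normalised values they were 665 and 845 (44% inside). Without a filter on low counts they were 1350 and 1685 (44.5% inside), and without the library block 457 and 489 (48.3% inside). The median log2 ratio of all tested genes was -0.06 with TMM and -0.40 with totals, so the changes above are relative to the TMM scale. Without well C the calls were 895 inside and 678 at the edge, and without well D 878 and 577. The contrast rested more on wells C and D, which held 139 and 140 interior spots, than on wells A and B with 23 and 32. Interior spots also held more UMIs, the ratio of the median interior to the median edge spot being 1.46 ± 0.271 (SD, n = 4). The log2 ratios of single wells correlated over the tested genes at r = 0.825 between wells C and D and at 0.408 to 0.457 between well A and the others.

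The second question was which genes were arranged in space at all, without any zone drawn beforehand. Moran's I, which is above its expected value when neighbouring spots have similar levels, was higher than expected for 412 of 5668 genes (limma over the 4 libraries, Benjamini-Hochberg adjusted p under 0.05). Their median excess I was 0.109, against 0.0198 for all genes tested, and 401 of the 412 were positive in 4 of 4 libraries. DJKW.24241 had the highest value, 0.377 ± 0.071 (SD, n = 4, limma adjusted p = 1.93e-06), and ranged from 0.273 to 0.423 across wells. DJKW.24391 was next at 0.362 ± 0.189 (limma adjusted p = 9.82e-05), ranging from 0.220 to 0.636. The order turned without well C (0.362 for DJKW.24241 and 0.398 for DJKW.24391) and without well D (0.361 and 0.369). Of the 412 genes, 185 were also called higher inside and 118 higher at the edge, while 109 were not called between these zones. The called share was 73.5% of the 412 genes and 28.5% of all 5668. DJKW.24241 was higher at the edge by a small margin (log2 fold change -0.62 ± 0.10, edgeR adjusted p = 3.26e-04) and DJKW.24391 higher inside (0.70 ± 0.15, edgeR adjusted p = 3.64e-03). Without well C 214 genes passed and without well D 248. With wells C and D alone 832 passed, but so few libraries give little measure of a gene's own spread. The higher count is therefore not shown to mean more structure in these wells. The count fell to 50 with neighbours up to 2 steps, where DJKW.24391 missed the threshold (limma adjusted p = 0.0656), to 103 with values centred within groups of connected spots, and to 86 of 1495 genes with spots thinned to 1613 UMIs. In simulated sections the test found 54.3% of genes 8-fold higher inside and 12.8% of those 4-fold higher among genes of at least 2000 UMIs. It found 4.04% of those 2-fold higher in another simulation with less abundant genes included, so a gene that did not pass is not shown to lack a spatial pattern.

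The third step divided the spots into regions of like expression, from a random 50% of the UMIs, and described each region with the remaining UMIs. The 1216 spots fell into 9 regions, numbered by size and called by their leading genes, which describe the regions and are not separate findings. Region 1, led by DJKW.10818 and DJKW.7912 (11.5-fold and 11.1-fold above the other spots), took a larger share of interior than of edge spots. Its spots numbered 163 inside and 70 at the edge, with 10 and 22 in well A and 21 and 20 in well B. It had spots in 48 of 48 sections and made up 50.9% ± 11 of interior spots but 8.94% ± 4.77 of edge spots (SD, n = 4). Region 2, led by DJKW.14455 (20-fold) and DJKW.26548 (11.1-fold), lay on the rim. It made up 23.8% ± 2.56 of edge spots and held 1 of the 334 interior spots. Region 4, led by DJKW.24604 (15.1-fold) and DJKW.13408 (8.04-fold), was also confined to the rim in these libraries, with 0 of 334 interior spots, which allows a share of up to 0.898%. Region 7, led by DJKW.5118 (20.9-fold) and Maker00011792 (19.5-fold), made up 8.44% ± 3.71 of edge spots and 0.36% ± 0.41 of interior spots.

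The regions also differed in where along the sections they lay. The sections were longer along the array rows, and 92.2% ± 9.69 (SD, n = 4) of the section spots of region 7 lay in the outer parts of that length, against 41.3% ± 6.49 of all section spots. Region 2 lay there with 70.4% ± 11 of its spots and region 1 with 13.3% ± 9.80. The ends hold more edge spots, regions 2 and 7 lay almost wholly at the edge, and region 1 lay mostly inside. Part of these differences may therefore follow from the zones, and shares among edge spots alone were not computed. Across the width, 90.8% ± 7.30 of the spots of region 4 and 82.1% ± 10.3 of those of region 6, led by DJKW.17074 (8.39-fold) and DJKW.10992 (8.29-fold), lay on the side of lower array columns, here called left. Region 5, led by DJKW.24997 and DJKW.14309 (both 13.2-fold), had 20.6% ± 16.1 of its spots on the left, where well A contributes 2 spots. In each of these 3 regions all 4 libraries leaned the same way, and the exact two-sided sign-flip test against 50% gave the smallest p that 4 libraries allow, which is above 0.05. The same held in the exact sign-flip test of the interior against edge shares of regions 1, 2, 4 and 7.

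**Figure D2:**
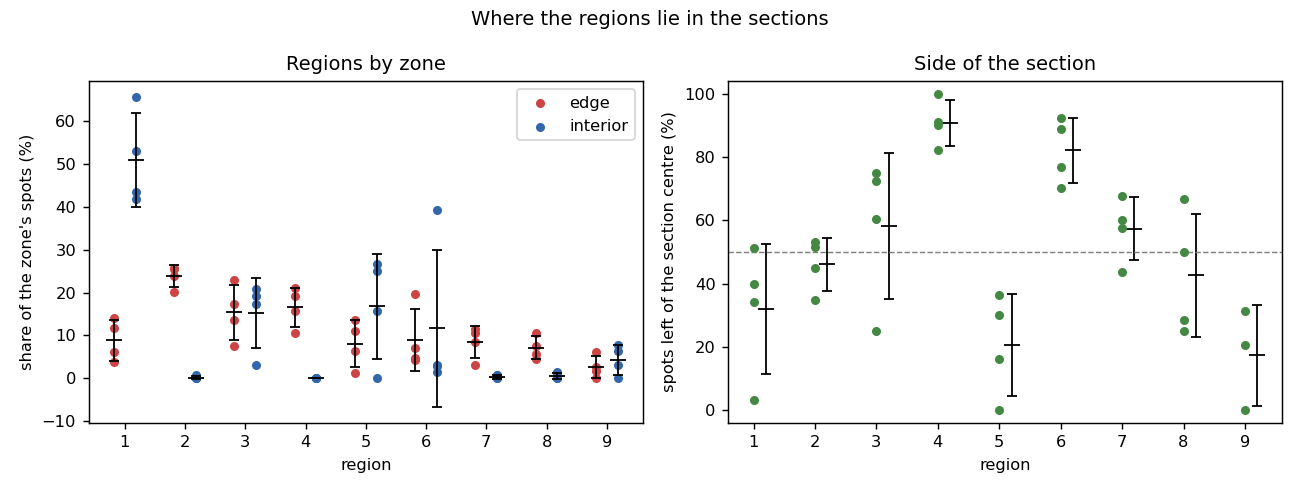
Left, the share of edge and of interior spots that each region took in each well, in percent. Right, the share of each region's section spots on the side of lower array columns, in percent, with 50% dashed. Points are wells and bars the mean ± SD. Region 1 takes 50.9% of interior spots and 8.94% of edge spots, and regions 4 and 6 lie mostly on the left.

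On the UMIs kept for testing, edgeR's quasi-likelihood test with the library as a block found 1130 genes higher in region 1 than in all other spots. It found 426 in region 2, 340 in region 3, 678 in region 4, 135 in region 5, 280 in region 6 and 58 in region 7, at an adjusted p under 0.05. Both sets of UMIs come from the same spots, so genes that formed a region differ in the testing set too. These counts therefore describe the regions and do not test whether they exist. Region 3, led by Maker00013522 (2.28-fold) and DJKW.22163 (2.16-fold), had the mildest leading genes and was spread over edge (15.4% ± 6.39) and interior (15.2% ± 8.15). Its count was 583 without well A, 34 without well C and 41 without well D. Genes lower in region 3 numbered 697, and 851 without well A, 286 without well C and 369 without well D. Without well D, region 2 had 283 genes higher and region 4 had 423. Region 5 was tested in 3 libraries. Region 8 was not tested because its summed counts were too small. Its median spot held 508 UMIs and 38 of its 62 spots lay off the sections. Region 9 had 49 spots, 45 of them in wells C and D, and was not tested. Well A held 0 of 180 spots of region 9, which allows a share of up to 1.67%. The borders of the regions depended on the settings. The adjusted Rand index with the partition above, which is 1 for identical partitions, was 0.594 with another seed, 0.487 with 10 principal components, 0.489 at resolution 1.0, 0.498 without spots off the sections and 0.357 without centring per library. Whether the leading genes of the regions stayed the same was not measured.

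**Figure D3:**
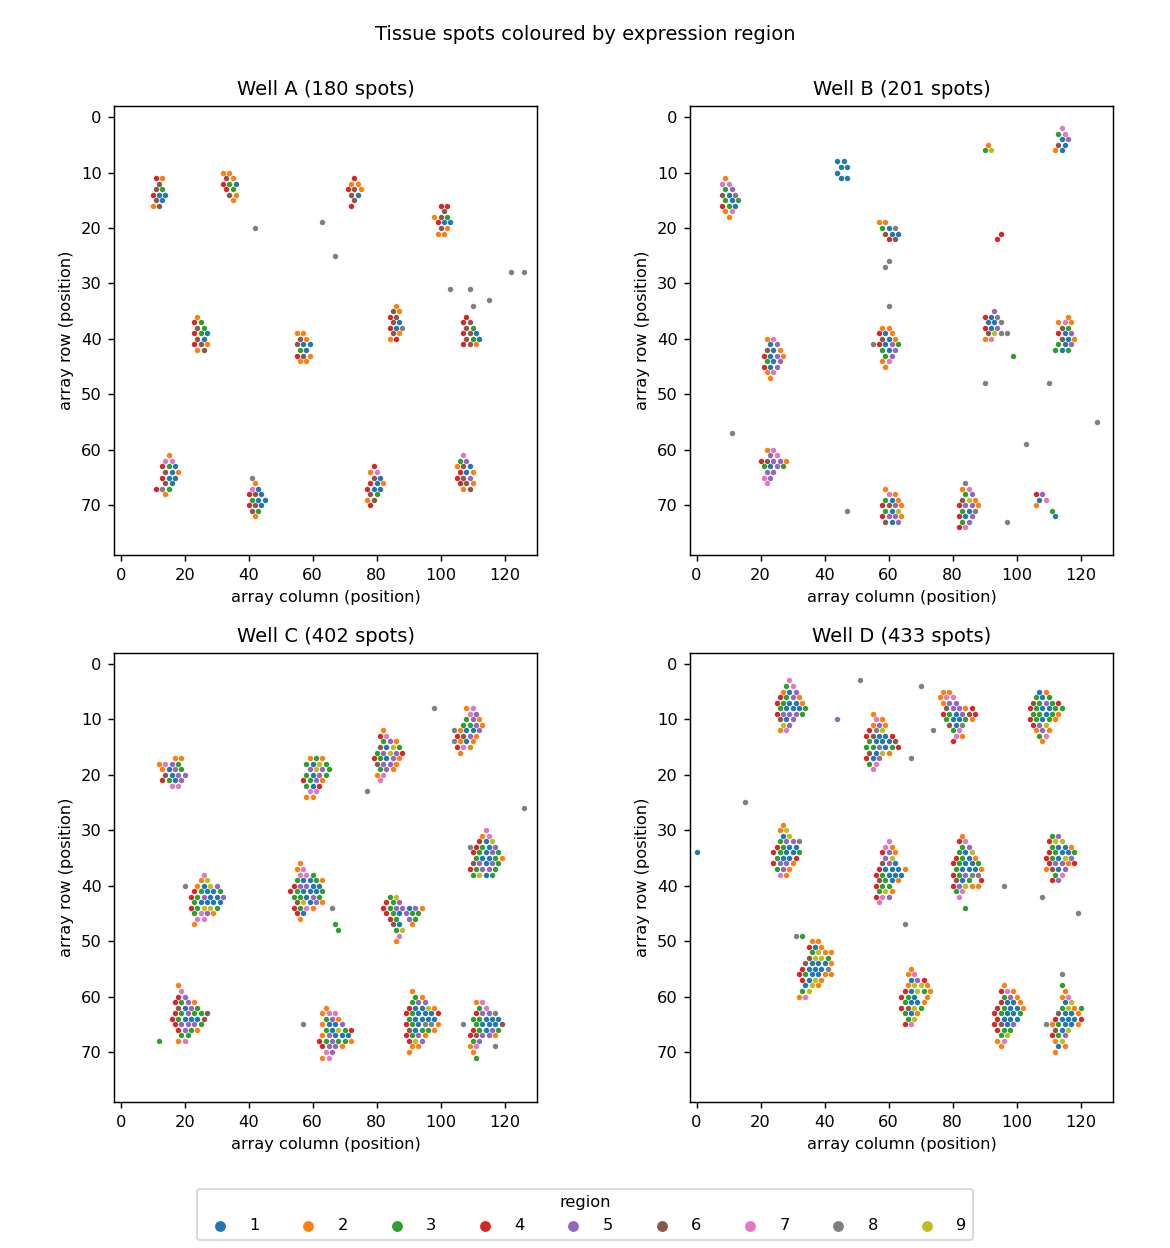
Positions of all 1216 tissue spots on the arrays of the 4 wells, by array column and array row, coloured by region. Region 1 takes 163 of the 334 interior spots, and regions 2 and 7 lie along their rims and tips, and 38 of the 53 spots off the sections belong to region 8.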

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

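Of 23 sets of 4 library values checked for a library far from the other 3, a single set held one, while chance alone gives about 1.15. Region 6 took 22.2% of the spots of well A (40 of 180, exact binomial 95% interval 16.4% to 29.0%) and between 3.23% and 6.47% of those of wells B, C and D.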

How the results depend on the processing

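The alternatives without wells A and B, without isolated spots, with spots matched by UMIs or with permutations within pieces, and the comparisons of section parts, were chosen after seeing the data. No gene called between edge and interior was called in the opposite direction in any alternative run. The direction of genes that missed the threshold in an alternative was not checked. The number higher at the edge moved to 736 with DESeq2, 2865 with library totals, 489 without the replicate block, 730 with as many edge spots as interior spots matched by UMIs (fewer spots, 7002 genes tested) and 642 with the interior set at least 2 steps from the edge (wells C and D alone, 7830 genes tested). The number higher inside moved to 802 with totals, 457 without the block and 665 with limma on means over spots. Leaving out 1 library gave 878 to 1795 genes higher inside and 577 to 1550 higher at the edge, and the counts without wells A and B both, 1677 and 1675, were within 1.5 times. Of 68 values of the 4 named genes under alternatives, 66 stayed past the threshold with their direction. Their size fell with limma on means over spots, to 1.06 for DJKW.7912, 0.98 for DJKW.24046, -0.61 for DJKW.26548 and -0.62 for DJKW.11951. The exceptions were DJKW.7912 and DJKW.24046 without the replicate block (edgeR adjusted p = 0.139 and 0.211, log2 fold changes 2.95 and 2.85), whose levels differ between wells. Genes with spatial structure numbered 50 with neighbours up to 2 steps and 103 with values centred within pieces. They numbered 86 with spots thinned to 1613 UMIs (1495 genes tested) and 214 to 526 when 1 library was left out. Without wells A and B they numbered 832, a count that rests on wells C and D alone. Centring within small pieces by itself lowers I, the median over all genes being -0.031. Once permutations within pieces were subtracted 386 genes passed, 302 of them also in the main run. DJKW.24391 missed the threshold with neighbours up to 2 steps (limma adjusted p = 0.0656). The number of regions stayed within 1.5 times under every clustering setting run (7 to 13), while the adjusted Rand index with the first partition was 0.357 to 0.623. Without the replicate block, genes higher in the region numbered 615 in region 1, 117 in region 2, 0 in region 3 (edgeR, 831 genes in either direction at an unadjusted p under 0.05), 282 in region 4, 54 in region 5, 63 in region 6 and 13 in region 7. Leaving out 1 library gave 870 to 1296, 283 to 526, 34 to 583, 423 to 907, 114 to 193, 211 to 247 and 50 to 80 in that order. The comparisons of section parts gave 465 to 1339 genes for left against right and 136 to 600 for middle against ends when 1 library was left out, and 136 for middle against ends on edge spots alone. Except where the smaller number of genes or libraries is given, the cause was not tested. The median correlation between libraries was 0.921, and 0.913 after thinning to the lowest total. Wells A and B held the fewest spots and UMIs. The list tests and Tcf4 could not be run.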

Other observations

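The comparisons between sides and between the middle and the ends of sections, the alternative without isolated spots and the matching of spots by UMIs were chosen after the data had been seen. The tests by random draws for Moran's I and by swaps for the regions, and the test of the library size of well A, were chosen after their results were known.

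The left and right sides of the sections differed in expression. With each section split at its mean array column, 811 genes were higher on the right and 574 on the left among 8432 tested (edgeR's quasi-likelihood test with the library as a block, adjusted p under 0.05), and 1328 of these 1385 went the same way in 4 of 4 libraries. DJKW.6593 stood at 8420 ± 7785 CPM on the right and 1244 ± 953 on the left (SD, n = 4, 7.90-fold, edgeR adjusted p = 3.31e-03). DJKW.7323 stood at 1774 ± 1692 CPM on the right and 239 ± 167 on the left (7.07-fold, edgeR adjusted p = 5.21e-04). DJKW.26548, a leading gene of the edge and of region 2, stood at 702 ± 159 CPM on the left and 105 ± 48.2 on the right (7.03-fold, edgeR adjusted p = 2.06e-04). DJKW.10198 stood at 89.1 ± 17.2 CPM on the left and 12.3 ± 7.78 on the right (6.87-fold, edgeR adjusted p = 2.37e-04). Without well B 706 genes were called, without well C 919 and without well D 465. Between the upper and lower parts of the same sections 0 genes were called among 8394 (edgeR, 372 genes or 4.43% at an unadjusted p under 0.05, no other tool run).

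A candidate explanation is that the sections were laid the same way round, so that array columns follow 1 body axis. Genes called from the other 3 wells gave a score above 0, right over left, in 48 of 48 sections of the well left out, with well means between 1.47 and 2.03 on the log2 scale. The 0 genes between upper and lower parts argue against calls that any such split of a section would give, though this split cannot show a pattern that is symmetric about the middle. Flipping sides at random per section gave as many calls in 1 of 51 assignments, the real one (1385 genes, highest other 199). This argues against sides set by chance. Which body faces lie left and right is not in the labels and was not tested.

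The middle and the ends of the section rows differed in 428 genes, 178 higher in the middle and 250 at the ends (edgeR, 8264 tested), with 169 without well B and 136 without well C. Shuffling middle and ends within sections gave as many calls in 1 of 51 assignments, the real one (highest other 27). This argues against parts drawn at random from single spots. The shuffled parts are scattered, so it cannot show what other groups of neighbouring spots would give. Because the ends hold more edge spots, the comparison was repeated on edge spots alone, and it called 136 genes, 58 higher in the middle and 78 at the ends. Fewer than 50% of the calls is what was set beforehand as the outcome if the edge were the cause. The smaller sums of edge spots also lower the count, and no shuffle was run on edge spots alone.

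The difference between edge and interior was weighed against chance, depth and isolated spots. Shuffling zones among the spots of each section gave as many calls in 1 of 51 assignments, the real one (2493 genes, highest other 18). This argues against zones drawn at random from single spots. Shuffled zones are scattered while the real zones hold neighbouring spots, so the shuffle cannot show what other groups of neighbouring spots would give. Thinning both zones of a library to one total left 2187 called genes, but this equalises the sums and not the UMIs per spot, so it decides nothing about deeper interior spots. With each interior spot matched to an edge spot of its library by UMIs, 1764 genes were called, against a median of 1725.5 over 10 draws of as many edge spots at random (1474 to 1894). The ratio of median UMIs was then 0.997 to 1.08, so depth per spot is argued against as the cause. Without the isolated spots 2477 of the 2493 calls were kept with their direction, which argues against these spots as the cause. No biological explanation was tested, since no gene names were at hand. For Moran's I, permuting spots within libraries gave as many genes in 1 of 21 assignments, the real one (412 genes, highest other 1). This argues against spots placed at random. The permutation also removes differences between sections, so it does not separate these from patterns within a section. With values centred within pieces and permutations within pieces subtracted, 386 genes passed, of which 302 were among the 412. The rest of the 412 did not pass there. For the regions, the 8 or fewer swaps of labels are too few for a share under 0.05. Only 1 assignment, the real one, reached the real count in each region tested. The highest other was 263, in region 3 with 1037 real calls in both directions. The closest to the real count was in region 7, with 72 against 162. The regions were formed from the expression of these same spots, and a swap cancels the difference that formed them. The swaps therefore cannot test whether the regions arose by chance.

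Well A stood apart from the other wells. Of 2820 genes with a mean of at least 50 CPM, 106 were at least 4-fold lower in well A than in each other well and 9 at least 4-fold higher, while the same counts for wells B, C and D were at most 1. No test was run, since each well is 1 library. The median correlation across genes was 0.961 among wells B, C and D and 0.837 for well A with them, and this gap remained 0.116 after thinning to one total, which argues against library size. On an axis from the mean section of well A (0) to that of well D (1), sections of well B averaged 0.655 ± 0.112 and those of well C 0.960 ± 0.064 (SD, n = 12). A hypothesis is that smaller sections may lie at another level of the body, which predicts that section size and axis score move together within each well. The wells with larger sections also held more interior spots (23 of 180 spots in well A and 140 of 433 in well D). Many genes differed between edge and interior, so size and score could move together through the zones alone. The correlation cannot tell this from body level.

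Over the 12 sections of a well, whose number is not certain in well B, the correlation of size with the axis score was positive in 3 of 4 wells and not in 4 of 4 as predicted. Correlations that differ in sign between wells, as here, were set beforehand as the outcome if the hypothesis were wrong. The negative value of well D did not pass 0.05, and sections of a well are not independent samples, so the hypothesis stays open. Pearson's r was 0.794 in well A (permutation p = 0.0017, adjusted over 4 wells 0.0068), and 0.732 without the 2 sections farthest from the median size. It was 0.435 in well B (permutation p = 0.157, adjusted 0.157), and 0.862 without 2. It was 0.494 in well C (permutation p = 0.1, adjusted 0.133), and 0.674 without 2. It was -0.515 in well D (permutation p = 0.0864, adjusted 0.133), and -0.388 without 2. Spearman's rho was 0.784, 0.418, 0.634 and -0.383 in that order (permutation p = 0.0031, 0.170, 0.0289 and 0.221, adjusted 0.0124, 0.221, 0.0578 and 0.221). In well A, both size and score also followed the place on the array. Its sections at the highest array rows held 16 to 18 spots and scored 0.055 to 0.245. Those at the lowest rows held 10 to 13 spots and scored -0.162 to 0.003. The permutations did not allow for place on the array, so the correlation in well A may reflect it. Well and body level cannot be told apart here, because each well is a single library.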
